A study of Homo sapiens with 9 samples.

How the data were processed

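The 9 libraries comprised 3 groups of 3, double positive, ABCA3 single positive and double negative cells sorted on day 36, each assigned from its own title in the labels. The values are FPKM (fragments per kilobase of exon length and depth), as deposited by the authors in 1 table of 16994 rows. GRCh38, STAR 2.5.2b, featureCounts of Subread 1.6.2 and edgeR 3.25.10 are named as the authors' tools and build, per the submitters' processing notes, with no role or order given. The annotation release, filters and the strand setting of the counting are not given in the sources used here, so fragments of overlapping genes on opposite strands could not be told apart.

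Of the rows, 14702 were annotated as protein coding, 1346 as antisense and 945 as lincRNA, and 1 held the GFP reporter sequence. Identifiers of 16971 rows were found in GENCODE release 29 and the deposited length equalled its union of exons for 96.7% of rows, so coordinates are given on GRCh38 from that release. 10 symbols stood on 2 rows, and 14 rows were at 0 in all libraries. Multiplying FPKM by the deposited length gave whole multiples of 1 step in each library for 100% of values (within 0.01), so whole fragments could be recovered. These came to 29775434, 27578748 and 29627387 in double negative replicates 1 to 3, 30854501, 28904681 and 30159976 in single positive replicates and 23921963, 26505406 and 24793169 in double positive replicates. They amounted to 86 to 107.4% of the library size by which the authors had divided. Fragments without molecular identifiers are not independent molecules, so floors cover counting error only.

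Changes were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a trend) on log2(FPKM + 1), over the 12677 genes with FPKM of at least 1 in at least 3 libraries. All 9 libraries entered 1 fit with a mean per group and a shared estimate of the spread. Benjamini-Hochberg adjustment was made within each of the 3 comparisons, at 0.05. Gene lists fixed before the data were examined were tested with limma's camera (two-sided, preset correlation of 0.01, Benjamini-Hochberg over the 31 lists with at least 5 tested members), and again with a correlation estimated from the data. The lists covered AT2, AT1, transitional, airway, ciliated, neuroendocrine, hepatic and intestinal, gastric, mesenchymal, endothelial and blood, and pluripotency markers, lung transcription factors, cell cycle, lipid and lysosome genes, signalling targets, stress, immune, metabolic, junction and histone genes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used for tables and plots.

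The genes named in the text were chosen by a rule set before the data were examined. Per comparison it took the 12 largest changes in each direction among genes that passed, whose groups did not overlap and whose higher group had a mean of at least 10 FPKM, leaving out clone names, pseudogenes, histones and sex-linked markers, together with SFTPC and ABCA3, and for each list described the members with the smallest adjusted p and the leading member of the other sign. Not every gene the rule selects is printed. Genes whose levels show sequence sharing with close relatives or overlap with neighbours are named as uncertain.

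The fits were tested on simulated data made from the deposited values, with 200 of 12677 genes changed. In the comparison of double positive with single positive cells 10%, 68%, 94% and 100% of genes changed 1.25-, 1.5-, 2- and 4-fold were recovered, and 11 unchanged genes were called. For double positive against double negative cells the shares were 10%, 54%, 100% and 100% (7 unchanged genes called), and for single positive against double negative cells 8%, 56%, 100% and 100% (11 unchanged genes called). The simulated noise had the same spread per gene in all 9 libraries. In the data the SD of a library's deviation from the others of its group ran from 0.127 (double negative replicate 2) to 0.399 (double positive replicate 2). These shares and false calls therefore hold for equal spreads and may not hold for the comparison of double with single positive cells. A simulated list of 30 genes raised by 0.3 on the log2 scale was called in 50 of 50 simulations and an unchanged list in 1 of 50. Simulated genes varied independently, so these simulations could not test the preset correlation. Estimated from the data, the correlation reached 0.614 (nuclear oxidative phosphorylation list).

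Alternatives planned before the data were examined were pseudocounts of 0.1 and 0.5, no filter, a filter of 5 FPKM, rescaling to TPM, median ratio scaling, limma without the trend and with array weights, fits of the 6 libraries compared, a replicate block, leaving out each library in turn and the estimated correlation. Added after seeing the data were limma-voom on the recovered fragments, removal of each library's trend with gene length, and that removal without double positive replicate 2.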

Results

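Gene expression was measured by poly(A) RNA sequencing in cells derived from RUES2, a human embryonic stem cell line. The clone used carried a tdTomato reporter of SFTPC, the surfactant protein C gene expressed by alveolar type II (AT2) cells, and a GFP reporter of ABCA3, the lipid transporter of the lamellar bodies in which AT2 cells store surfactant. Cells were taken through a distal lung differentiation, enriched on the way for progenitors of the NKX2-1 lung lineage, and sorted by flow cytometry on day 36. The sort gave 3 groups of 3 libraries, namely cells positive for both reporters (double positive), cells positive for the ABCA3 reporter alone (single positive) and cells positive for neither (double negative). The comparisons ask how cells with both reporters differ from cells with neither, how cells with the ABCA3 reporter alone differ from cells with neither, and what distinguishes the reporter-positive gates from each other. The labels speak both of triplicate differentiations and of progenitors divided over 3 plates after the first sort. Whether replicates are separate differentiations or plates filled from the same sort is thus not settled. The p-values measure the spread between these cultures, which may not include the spread between differentiations.

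The libraries held between 23921963 (double positive replicate 1) and 30854501 (single positive replicate 1) fragments over the listed genes. In a transcript of 1 kb, 3 fragments corresponded to between 0.0866 FPKM (double negative replicate 1) and 0.128 FPKM (double positive replicate 1), a floor that covers counting error only. Levels are given as mean FPKM ± SD (n = 3), and fold changes as the difference of group means ± SE on the log2(FPKM + 1) scale, which understates the change of low genes.

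The sorted genes were examined first. SFTPC (ENSG00000168484, chromosome 8, 22156913 to 22164479) lay at 2.62, 0.424 and 0.49 FPKM in the double negative libraries, 169.5 ± 36.4 in single positive and 1551 ± 196 in double positive cells. ABCA3 (ENSG00000167972, chromosome 16, 2275881 to 2340746) lay at 1.43 ± 0.205, 281 ± 25.2 and 372 ± 120.4 FPKM in the same order, and the GFP reporter transcript at 1.2 ± 0.818, 259 ± 27 and 432 ± 66.7. Between the reporter-positive gates SFTPC differed by 3.20 ± 0.31 (limma adjusted p = 0.00112). ABCA3 differed there by 0.35 ± 0.21 (limma adjusted p = 0.3) and the GFP reporter by 0.73 ± 0.23 (limma adjusted p = 0.0708), neither of which passed the test. Without double positive replicate 2, in which ABCA3 stood at 235 FPKM against 462 and 419 in replicates 1 and 3, the ABCA3 difference was 0.65 (limma adjusted p = 0.00265). Over all 22 alternatives the limma adjusted p of ABCA3 ranged from 0.00265 to 0.598. The GFP difference passed without double negative replicate 1 (limma adjusted p = 0.0364) and without double negative replicate 3 (limma adjusted p = 0.048), with a range from 0.0128 to 0.233 over the alternatives. An exact permutation test of 3 against 3 libraries cannot go below 0.1. These genes were sorted on and are no finding of the comparisons.

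**Figure D1:**
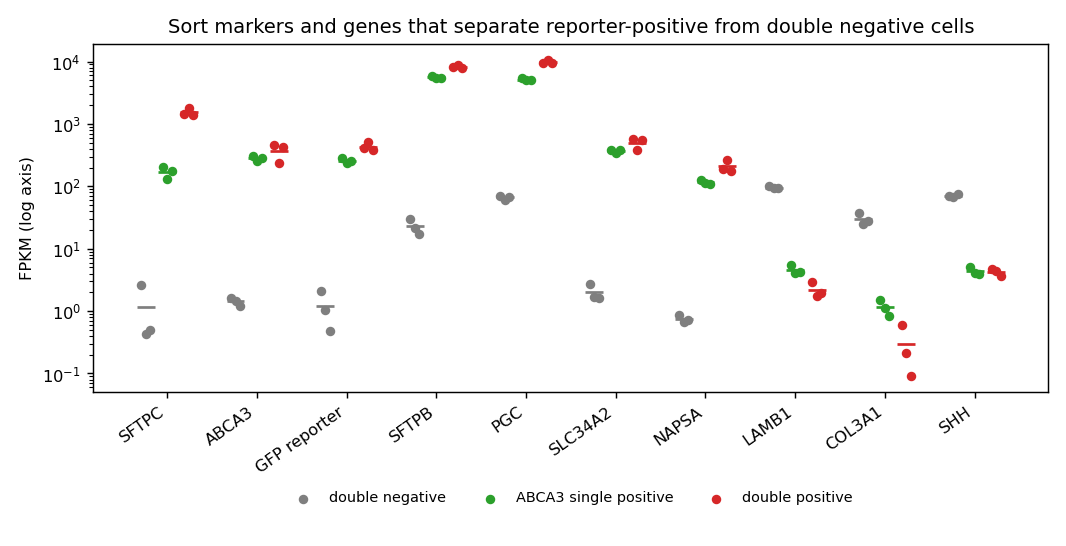
FPKM on a log axis of the sort markers and of genes that differ between reporter-positive and double negative cells, with 1 point per library (3 per group) and a line at each group mean. SFTPC rises from 1.18 to 169.5 and 1551 FPKM across the gates, while LAMB1 falls from 95.7 to 4.61 and 2.2.

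Double negative cells stood far from both reporter-positive groups, and single and double positive cells lay close together. The first principal component held 81.3% of the variance and placed double negative libraries at -60.6 to -60.1, single positive libraries at 23.4 to 24.4 and double positive libraries at 35.8 to 38.1. Pearson correlations of log2 values across genes, which are not independent replicates, were 0.995 among double negative libraries, 0.828 to 0.841 between double negative and double positive libraries, and 0.956 to 0.985 between double and single positive libraries. Double positive replicate 2 stood apart on the second component (9.3% of the variance), at 36.5 against -15.1 to 2.4 for the other libraries. Its correlations with double positive replicates 1 and 3 were 0.968 and 0.969. Those replicates correlated more closely with each single positive library, at 0.975 to 0.985.

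**Figure D2:**
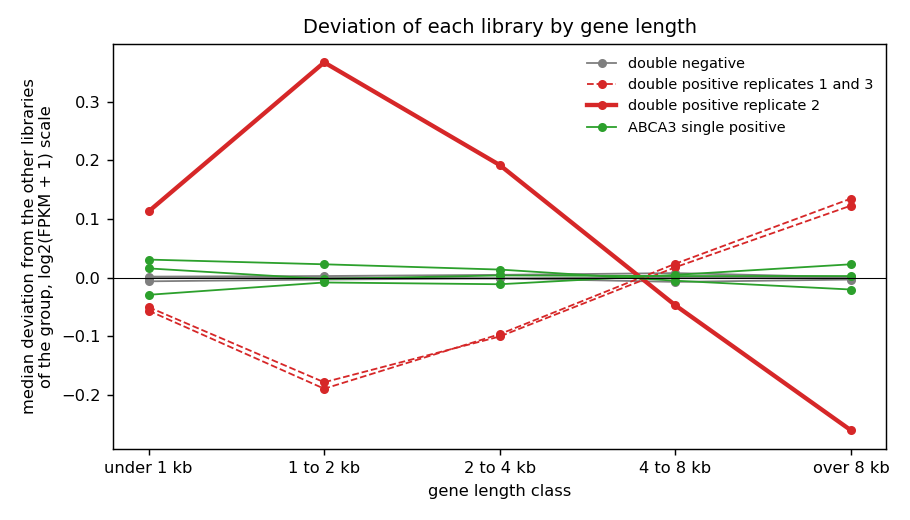
Median deviation of each library from the other libraries of its group, on the log2(FPKM + 1) scale, over 5 classes of gene length, with 1 line per library. Double positive replicate 2 runs from 0.37 at 1 to 2 kb to -0.26 above 8 kb, while the double negative and single positive libraries stay between -0.03 and 0.03.

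Cells with both reporters carried the surfactant programme at levels far above those of double negative cells. SFTPB, which encodes surfactant protein B (ENSG00000168878, chromosome 2, 85657314 to 85668741), rose from 22.7 ± 6.34 to 8278 ± 567 FPKM, a log2 fold change of 8.48 ± 0.17 (limma adjusted p = 4.15e-10). PGC, the pepsinogen C gene, which AT2 cells also express (ENSG00000096088, chromosome 6, 41736711 to 41754109), rose from 66.2 ± 5.12 to 9856 ± 701 FPKM. SLC34A2, a phosphate transporter of AT2 cells, rose from 2.01 ± 0.602 to 502 ± 104, and NAPSA, an aspartic protease that processes surfactant protein B, from 0.754 ± 0.109 to 210.4 ± 48.2. Further genes with large increases were SFTPA1 (7.26), SLPI (6.88), CHI3L2 (6.64), RNASE1 (6.04) and NMU (6.03), given as log2 fold changes. SFTPA1 shares sequence with SFTPA2, so its level is uncertain.

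Genes of laminin, collagen and sulphotransferases were among the 12 that fell most. LAMB1 and LAMA1, chains of embryonic laminin, went from 95.7 ± 3.44 to 2.2 ± 0.612 FPKM and from 40.6 ± 4.15 to 1.98 ± 0.402 FPKM. The sulphotransferase genes SULT1E1 and SULT1C4 fell by 4.90 and 3.78 on the log2 scale, while the fibrillar collagen gene COL3A1 changed by -4.58. PLA2G2A, a secreted phospholipase, went from 478 ± 18.7 to 19.4 ± 3.13 FPKM and TBX3, a transcription factor of development, from 61.4 ± 4.89 to 2.79 ± 0.547 FPKM. The rest of the 12 largest decreases were LCN15 (-4.71), CAMK2N1 (-4.60), LYZ (-3.99), SMOC2 (-3.91) and POF1B (-3.86), with limma adjusted p of at most 7.62e-08.

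Among the gene lists fixed before the data were examined, the AT2 list moved most. All 29 tested members rose, by a median of 4.69 (camera adjusted p = 5.25e-20, and adjusted p = 0.0112 with an estimated correlation). Of 37 listed genes, 36 were among the deposited rows and 29 passed the filter, which can keep a gene through the reporter-positive libraries alone. Below the filter, HHIP, DMBT1, ALPL, AQP1 and ZMAT4 had lower means in double positive cells and CD36 and RASGRF1 higher ones. The list includes SFTPC and ABCA3, whose reporters defined the gates. MUC1, a membrane mucin, rose from 1.48 ± 0.111 to 70.9 ± 0.264 FPKM and LPCAT1, which makes the dipalmitoyl lecithin of surfactant, from 17.7 ± 0.949 to 482 ± 37.5. Lipid synthesis moved with it. Of 30 fatty acid and phospholipid genes 23 rose and 3 fell, or 23 and 4 when adjusted over the list alone (camera adjusted p = 7.33e-07, and adjusted p = 0.0112 with an estimated correlation). FASN, the fatty acid synthase, went from 95.5 ± 10.8 to 1836 ± 286 FPKM and ACSL1, an acyl-CoA synthetase, from 9.14 ± 0.296 to 191 ± 26.1, whereas PPARG, a regulator of lipid storage, went from 10.4 ± 0.275 to 0.517 ± 0.21. Of 24 cholesterol synthesis genes 23 rose and none fell, the same number when adjusted over the list alone (camera adjusted p = 2.51e-08, and adjusted p = 0.0112 with an estimated correlation). LSS, the lanosterol synthase, went from 15.2 ± 1.3 to 63.1 ± 5.47 FPKM and MVK, the mevalonate kinase, from 2.91 ± 0.196 to 10.2 ± 0.589.

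Genes of lysosomes and secretory vesicles, which include the organelles related to lamellar bodies, rose as well. Of 34 tested members 29 rose and 3 fell, with the same counts when adjusted over the list alone (camera adjusted p = 6.09e-08, but adjusted p = 0.0777 with an estimated correlation). CTSH, a cathepsin that processes surfactant protein B, went from 14.6 ± 0.502 to 345 ± 72.8 FPKM, ASAH1, an acid ceramidase, from 6.24 ± 0.157 to 46.8 ± 3.05, and SYTL2, a vesicle tether, from 2.02 ± 0.0866 to 0.946 ± 0.0878. Of 24 NF-kappaB targets and inflammatory mediators 20 rose and 2 fell, unchanged when adjusted over the list alone (camera adjusted p = 1.03e-05, but adjusted p = 0.375 with an estimated correlation). The chemokine genes CXCL17 and CXCL2 went from 0.382 ± 0.102 to 69.1 ± 14.9 FPKM and from 53.5 ± 2.91 to 688 ± 141 FPKM, and IL1A from 2.02 ± 0.378 to 0.255 ± 0.328.

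Another 4 lists rose with larger camera p-values. ER stress genes rose in 19 and fell in 2 of 29 members, or 21 and 3 when adjusted over the list alone (camera adjusted p = 0.000864, but adjusted p = 0.246 with an estimated correlation). EDEM1, which sends misfolded proteins to degradation, rose by 1.24 and ATF3, a stress-induced transcription factor, fell by 1.03 on the log2 scale. Antigen presentation genes rose in 10 and fell in 1 of 13 members, or 10 and 2 when adjusted over the list alone (camera adjusted p = 0.00705, but adjusted p = 0.383 with an estimated correlation). The members with the smallest p were of class I presentation, HLA-B (2.62, uncertain because HLA genes share sequence) and TAPBP (1.26), while CD74, the class II invariant chain, went from 15.5 ± 0.661 to 6.75 ± 2.0 FPKM. Alveolar type I (AT1) markers rose in 14 and fell in 3 of 21 members, or 14 and 3 when adjusted over the list alone (camera adjusted p = 0.00913, but adjusted p = 0.116 with an estimated correlation, and 0.336 among genes of at least 5 FPKM in 3 libraries, the highest of a range from 0.000942). HOPX, a homeodomain cofactor, went from 0.272 ± 0.0211 to 47.7 ± 9.71 FPKM and SPOCK2, a matrix proteoglycan, from 5.83 ± 0.532 to 0.333 ± 0.0426. Targets of glucocorticoid and cyclic AMP, whose agonists were in the medium of all groups, rose in 12 and fell in 5 of 20 members. The counts were 12 and 5 when adjusted over the list alone. The camera adjusted p was 0.0268, but 0.177 with an estimated correlation. With the preset correlation it was 0.1 without a filter on low genes, the highest of a range from 0.00131 over those alternatives. KLF9 rose by 2.54 and NR4A1 fell by 1.19 on the log2 scale. With double positive replicate 2 left out, 2 antigen presentation genes fell, and 1 ER stress gene fell without any 1 of the double negative or single positive libraries.

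**Figure D3:**
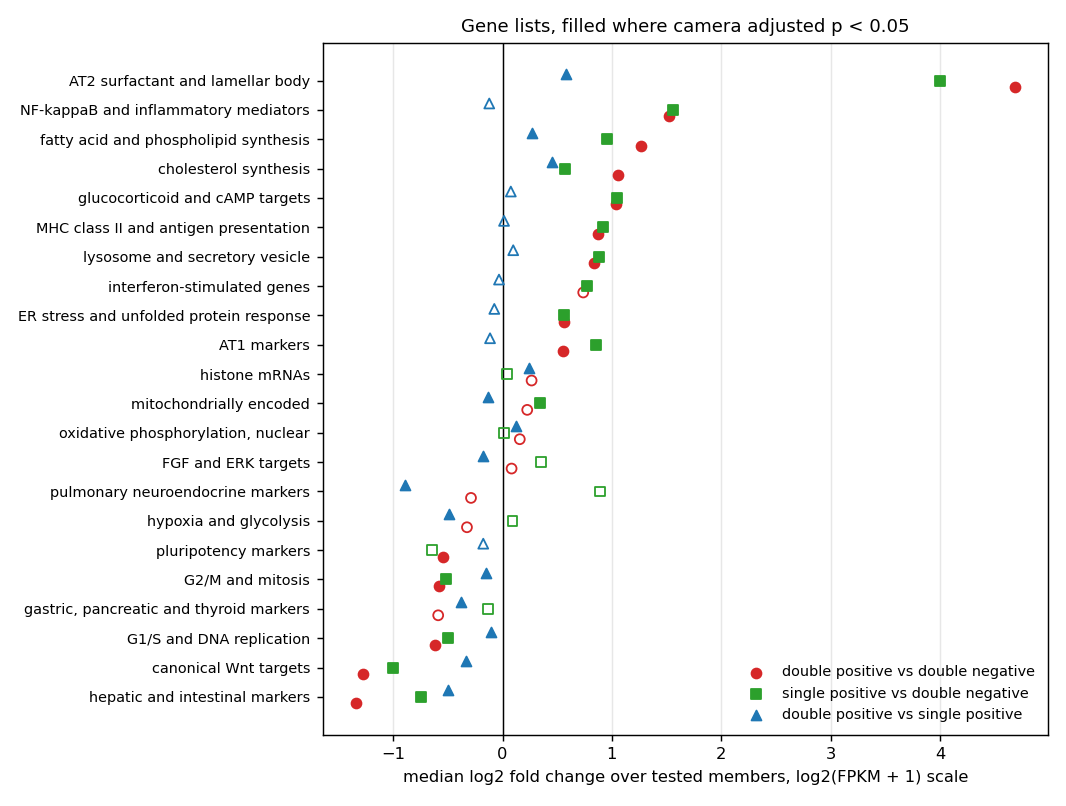
Median log2 fold change over the tested members of each gene list that passed in at least 1 comparison, on the log2(FPKM + 1) scale, with a symbol per comparison, filled where the camera adjusted p was under 0.05. The AT2 list lies farthest to the right, at 4.69 for double positive against double negative cells and 0.58 between the reporter-positive gates.

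Proliferation, Wnt target and gut genes were lower in double positive than in double negative cells. Of 38 mitotic genes 32 fell and none rose, or 32 and 1 when adjusted over the list alone (camera adjusted p = 6.57e-08, but adjusted p = 0.177 with an estimated correlation). CCNA2, cyclin A2, went from 19.6 ± 0.435 to 10.1 ± 0.649 FPKM. Of 32 replication genes 20 fell and 2 rose, or 20 and 2 when adjusted over the list alone (camera adjusted p = 0.000107, but adjusted p = 0.291 with an estimated correlation), with DTL at -1.23 and E2F1 at 0.77. Of 18 Wnt targets 15 fell and 3 rose, unchanged when adjusted over the list alone (camera adjusted p = 9.18e-05, but adjusted p = 0.177 with an estimated correlation). The R-spondin receptor LGR5 went from 8.84 ± 0.851 to 0.949 ± 0.243 FPKM and the Wnt inhibitor NOTUM from 37.4 ± 4.16 to 3.73 ± 1.16, while WIF1, an inhibitor that the AT2 list also holds, went from 11.8 ± 0.902 to 38.6 ± 4.34. Hepatic and intestinal markers fell in 19 and rose in 7 of 28 members, or 19 and 7 when adjusted over the list alone. The camera adjusted p was 0.000864, but 0.383 with an estimated correlation. With the preset correlation it was 0.0578 on the TPM scale, the highest of a range from 0.000422 over those alternatives. CDX2, a regulator of intestinal identity, went from 15.6 ± 0.309 to 0.401 ± 0.199 FPKM and CDH17, an intestinal cadherin, from 102 ± 5.82 to 8.25 ± 1.53, whereas FGA and FGG, fibrinogen chains, rose by 2.83 and 4.62. Without double negative replicate 3 the hepatic and intestinal markers that rose numbered 4. The replication genes that rose numbered 1 without any 1 of the double negative libraries or single positive replicates 1 and 3, and 1 mitotic gene rose without double positive replicate 1. Of 6 pluripotency markers 5 fell and 1 rose, with the same counts when adjusted over the list alone (camera adjusted p = 0.0494, but adjusted p = 0.177 with an estimated correlation). SALL4 went from 12.6 ± 0.572 to 2.58 ± 0.148 FPKM and L1TD1 from 0.29 ± 0.0307 to 1.05 ± 0.112. That call was lost without double negative replicate 1 (camera adjusted p = 0.0502), double positive replicate 1 (0.0573) or 2 (0.0519) and single positive replicate 1 (0.0573), 2 (0.0542) or 3 (0.0576). It was lost in 15 of 21 alternatives with the preset correlation, within a range of 0.0225 to 0.155. Among them were the replicate block (camera adjusted p = 0.0529), the 6 libraries compared (0.0604), median ratio scaling (0.0552) and TPM (0.155).

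The remaining 17 lists did not pass in this comparison, among them interferon-stimulated genes (9 rose and 2 fell of 13, camera adjusted p = 0.0605) and mesenchymal markers (2 and 7 of 12, 0.0605). Lung transcription factors went both ways, with 13 up and 9 down of 25 (camera adjusted p = 0.337). NKX2-1, the lung lineage regulator, rose from 5.6 ± 0.881 to 94.5 ± 3.28 FPKM and SOX9, a distal tip progenitor factor, went from 42.6 ± 2.71 to 7.32 ± 0.817. Hypoxia and glycolysis genes (camera adjusted p = 0.0893) and mitochondrially encoded genes (camera adjusted p = 0.12) passed without double positive replicate 2, at 0.0412 and 0.033. The interferon list passed without double negative replicate 2 (camera adjusted p = 0.044), on the TPM scale (0.0173) and with the filter of 5 FPKM (0.00957), and the hypoxia list with that filter (0.0393) and with array weights (0.0435). The camera adjusted p of the others was 0.218 for neuroendocrine, 0.292 for p53 target, 0.321 for histone, 0.337 for gastric, pancreatic and thyroid, 0.355 for junction, 0.367 for nuclear oxidative phosphorylation and 0.367 for ciliated genes. For transitional alveolar, airway, BMP and TGF-beta target, immediate early, and FGF and ERK target genes the camera adjusted p was 0.458, 0.475, 0.535, 0.641 and 0.839. The endothelial and blood list had fewer than 5 tested members and was not tested as a set; of these, LYZ went from 30.6 ± 2.95 to 1.02 ± 0.52 FPKM, CLDN5 from 0.301 ± 0.0897 to 8.0 ± 3.15 and CD68 from 26.8 ± 3.92 to 17.1 ± 4.35.

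Across all 12677 genes tested, 7407 (58.4%) passed the limma test, 3942 higher and 3465 lower in double positive cells, of which 1121 and 803 changed at least 2-fold on the log2(FPKM + 1) scale. The 3 and 3 libraries did not overlap for 8195 genes (64.6%, against 10% by chance). Rescaling each library to TPM moved the median fold change of all genes to -0.30. The counts then were 2414 higher and 5785 lower (29.4% higher, against 53.2% on the deposited scale), so directions of small changes depend on the scale. None of the 14 lists that passed changed the sign of its median under that scaling, and without double positive replicate 2 the count was 8336.

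Single positive cells also carried surfactant genes at levels far above those of double negative cells. SFTPB lay at 5635 ± 205 against 22.7 ± 6.34 FPKM, a log2 fold change of 7.93 ± 0.17 (limma adjusted p = 9.88e-10), and PGC at 5145 ± 199.8 against 66.2 ± 5.12 FPKM. SLC34A2 (6.97), SFTPA1 (6.21), NAPSA (6.07), SLPI (5.86), CHI3L2 (5.64), RNASE1 (5.38) and NMU (5.13) were among the largest increases beside the sort markers. SHH, the sonic hedgehog ligand, went from 71.2 ± 2.73 to 4.37 ± 0.616 FPKM and IRF8, a transcription factor of blood cells, from 14.5 ± 1.17 to 0.506 ± 0.186. FBLN2, a matrix protein, went from 19.8 ± 3.36 to 0.586 ± 0.157 FPKM. Further large decreases were LCN15 (-4.49), SULT1E1 (-4.28), LAMB1 (-4.12), CAMK2N1 (-3.86), COL3A1 (-3.85), LYZ (-3.65), PLA2G2A (-3.52) and SMOC2 (-3.38).

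Of the lists, all 29 tested AT2 genes rose (camera adjusted p = 1.2e-21, and adjusted p = 0.0191 with an estimated correlation). Lysosomal genes rose in 29 and fell in 1 of 34 members, or 30 and 3 when adjusted over the list alone (camera adjusted p = 6.32e-09, and adjusted p = 0.0473 with an estimated correlation). Fatty acid genes rose in 22 and fell in 3 of 30 members, 22 and 3 when adjusted over the list alone (camera adjusted p = 1.49e-06, and adjusted p = 0.0191 with an estimated correlation). Cholesterol synthesis genes rose in 17 of 24 members and fell in none, 17 when adjusted over the list alone (camera adjusted p = 2.2e-05, and adjusted p = 0.0229 with an estimated correlation). AT1 markers rose in 15 and fell in 3 of 21, 16 and 4 when adjusted over the list alone (camera adjusted p = 0.001, and adjusted p = 0.0473 with an estimated correlation, but 0.144 among genes of at least 5 FPKM in 3 libraries, the highest of a range from 4.9e-05). FASN lay at 1087 ± 83.5 against 95.5 ± 10.8 FPKM, CTSH at 249 ± 5.18 against 14.6 ± 0.502, LSS at 39.1 ± 4.04 against 15.2 ± 1.3 and HOPX at 21.4 ± 2.19 against 0.272 ± 0.0211. The lysosomal genes that fell numbered 3 without double positive replicate 2, and 2 without double positive replicate 1 or 3 or single positive replicate 1.

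A further 6 lists rose, each with a call that was lost with an estimated correlation. Inflammatory mediators rose in 19 and fell in 1 of 24 members (camera adjusted p = 2.34e-07, but adjusted p = 0.272 with an estimated correlation), led by CXCL17 (4.68) and ICAM1 (5.09). ER stress genes rose in 20 and fell in 1 of 29 (camera adjusted p = 0.000164, but adjusted p = 0.192 with an estimated correlation), with EDEM1 at 1.32 and ATF3 at -0.71. Glucocorticoid and cyclic AMP targets rose in 15 and fell in 5 of 20 (camera adjusted p = 0.00405, but adjusted p = 0.0642 with an estimated correlation), with KLF9 at 2.41 and CEBPD at 3.58. Antigen presentation genes rose in 9 and fell in 1 of 13 (camera adjusted p = 0.00414, but adjusted p = 0.348 with an estimated correlation). Interferon-stimulated genes rose in 9 with 1 falling of 13 (camera adjusted p = 0.00414, but adjusted p = 0.0642 with an estimated correlation), with IFI6 at 3.11. Mitochondrially encoded genes rose in 6 of 13 and fell in none (camera adjusted p = 0.00414, but adjusted p = 0.0642 with an estimated correlation), with MT-CYB at 0.60. Adjusted over the list alone, the counts that rose and fell were 19 and 1 for inflammatory, 20 and 1 for ER stress, 15 and 5 for glucocorticoid, 9 and 1 for antigen presentation, 9 and 1 for interferon and 6 and 0 for mitochondrial genes. Without double positive replicate 2, 13 mitochondrially encoded genes rose (camera adjusted p = 0.00058), and 2 rose without any 1 of the double negative replicates, single positive replicate 2 or single positive replicate 3. With double positive replicate 2 left out, 2 ER stress genes fell, and 2 antigen presentation genes fell without double positive replicate 1 or 2.

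The lists that fell were of proliferation, Wnt targets and gut. Mitotic genes fell in 29 and rose in 1 of 38 members, 32 and 1 when adjusted over the list alone (camera adjusted p = 7.63e-07, but adjusted p = 0.192 with an estimated correlation). The exception was UBE2C at 0.71. Replication genes fell in 20 and rose in 2 of 32, 20 and 4 when adjusted over the list alone (camera adjusted p = 0.000257, but adjusted p = 0.273 with an estimated correlation). The number that rose was 4 without double positive replicate 2, 1 without double negative replicate 1 or 2 or single positive replicate 2 or 3, and 0 without double negative replicate 3 or single positive replicate 1. Wnt targets fell in 12 and rose in 3 of 18, 14 and 3 when adjusted over the list alone (camera adjusted p = 0.000551, but adjusted p = 0.192 with an estimated correlation). LGR5 lay at 1.84 ± 0.142 against 8.84 ± 0.851 FPKM and CCND1, cyclin D1, at 106 ± 7.84 against 41.8 ± 3.31. Hepatic and intestinal markers fell in 17 and rose in 8 of 28, 17 and 8 when adjusted over the list alone (camera adjusted p = 0.0281, but adjusted p = 0.594 with an estimated correlation). CDX2 lay at 0.958 ± 0.097 against 15.6 ± 0.309 FPKM. This last call was also lost on the TPM scale (camera adjusted p = 0.286), with only the 6 libraries compared (0.0553) and without double positive replicate 2 (0.0573). Over the alternatives with the preset correlation its camera adjusted p ranged from 0.00627 to 0.286.

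In all, 6344 genes (50% of those tested) passed the limma test, 3381 higher and 2963 lower in single positive cells, with 928 and 568 changed at least 2-fold. The libraries did not overlap for 8843 genes (69.8%, against 10% by chance). On the TPM scale the median fold change of all genes was -0.22, with 2228 genes higher and 4846 lower (31.5% higher, against 53.3%). Of the lists that did not pass, neuroendocrine markers passed on the TPM scale (camera adjusted p = 0.0202, against 0.0936) and without a filter (0.0203), pluripotency markers without a filter (0.0299), and airway markers and p53 targets with the filter of 5 FPKM (0.0399 and 0.0471).

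The reporter-positive gates differed in far fewer genes, and genes of gut and endocrine cells were among the largest decreases. CHGA, the chromogranin A gene of endocrine secretory granules (ENSG00000100604, chromosome 14, 92923080 to 92935293), lay at 37.4 ± 11.9 FPKM in single positive and 0.289 ± 0.204 in double positive cells, against 8.98 ± 0.905 in double negative cells (log2 fold change -4.86 ± 0.21, limma adjusted p = 5.86e-06). APOA4, an apolipoprotein of intestinal absorptive cells (ENSG00000110244, chromosome 11, 116820700 to 116823306), lay at 64.2 ± 12.3 and 10.8 ± 2.42 FPKM. MUC13, a membrane mucin of the gut, lay at 60.8 ± 15.2 and 13 ± 3.3 FPKM and RBP2, an intestinal retinol carrier, at 29.5 ± 6.65 and 6.5 ± 0.782. Further genes lower in double positive cells were CLCA1 (-2.75), ANPEP (-2.12), GSTA1 (-1.90, uncertain because GSTA genes share sequence), APOB (-1.54), CDH17 (-1.42) and SPINK1 (-1.33).

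Among genes higher in double positive cells, SFTPD, which encodes surfactant protein D, lay at 34 ± 6.84 against 13.7 ± 3.65 FPKM in single positive cells (log2 fold change 1.27 ± 0.19, limma adjusted p = 0.00741). PEBP4, a gene of the AT2 list, lay at 20 ± 7.38 against 7.19 ± 1.03 FPKM, HOPX at 47.7 ± 9.71 against 21.4 ± 2.19 and ALB, the albumin gene, at 56.4 ± 21.3 against 19.9 ± 0.983. SNHG25 (1.71), BEX1 (1.22), FKBP2 (1.18), PLA2G1B (1.14), BMP1 (1.03), SLPI (1.01) and CHI3L2 (1.00) completed the 12 largest with SFTPC. BMP1 starts 257 bases beyond the end of SFTPC, so its fragments may not all be its own.

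**Figure D4:**
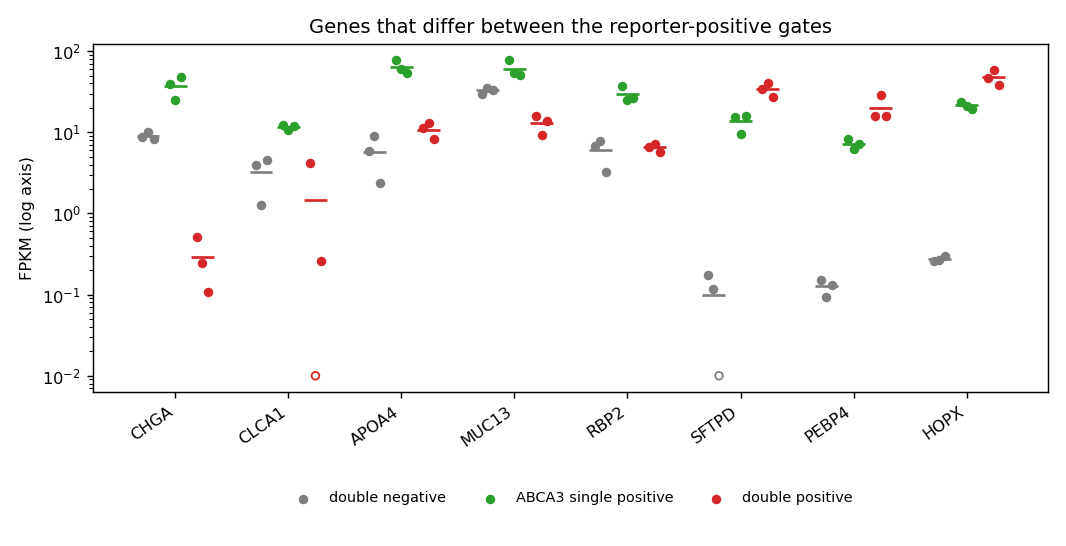
FPKM on a log axis of 8 genes that differ between double and single positive cells, with double negative cells beside them, 1 point per library (3 per group) and a line at each group mean; open points at the lower edge are libraries at 0. CHGA drops from 37.4 FPKM in single positive to 0.289 in double positive cells, and SFTPD goes from 13.7 to 34.

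Lipid and surfactant lists were higher in double positive cells. AT2 genes rose in 13 of 29 members and fell in none, 21 when adjusted over the list alone (camera adjusted p = 2.75e-12, and adjusted p = 0.0242 with an estimated correlation). They included SFTPC itself and MFSD2A, a lysolipid transporter, at 73.7 ± 7.34 against 39.4 ± 6.0 FPKM. Cholesterol synthesis genes rose in 13 of 24 and fell in none, 19 when adjusted over the list alone (camera adjusted p = 2.47e-11, and adjusted p = 0.00704 with an estimated correlation). MVD of the mevalonate pathway lay at 58.2 ± 6.28 against 28.9 ± 4.31 FPKM. Fatty acid genes rose in 9 and fell in 1 of 30, 17 and 1 when adjusted over the list alone (camera adjusted p = 2.08e-06, and adjusted p = 0.0204 with an estimated correlation). ACSS2, which makes acetyl-CoA, lay at 96.9 ± 3.92 against 55.2 ± 3.6 FPKM. These counts moved with single libraries. Without double positive replicate 2 the AT2 count was 20, the cholesterol count 19 and the fatty acid counts 19 up and 2 down. The numbers that rose were 8, 7 and 4 without single positive replicate 2 and 8, 6 and 3 without single positive replicate 3, in the same order. The fatty acid count that rose was 5 without double negative replicate 1, 2 or 3, and the gene that fell passed with none of the libraries other than double positive replicate 2 left out.

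Neuroendocrine, hypoxia, Wnt target and gut lists were lower in double positive cells. Neuroendocrine markers fell in 6 of 10 members and rose in none, 7 and 1 when adjusted over the list alone (camera adjusted p = 1.16e-06, and adjusted p = 0.0242 with an estimated correlation). PCSK1, a prohormone convertase, lay at 0.0388 ± 0.0339 against 1.98 ± 0.322 FPKM and SCG2, a granin, at 0.336 ± 0.0758 against 1.96 ± 0.395. Hypoxia and glycolysis genes fell in 13 of 27 and rose in none, 17 when adjusted over the list alone (camera adjusted p = 3.55e-10, but adjusted p = 0.207 with an estimated correlation). The glucose transporter SLC2A1 lay at 57.5 ± 7.11 against 126 ± 9.05 FPKM and the hexokinase HK2 at 5.04 ± 0.933 against 11.7 ± 0.122. Wnt targets fell in 7 of 18 and rose in none, 10 when adjusted over the list alone (camera adjusted p = 2.1e-05, but adjusted p = 0.157 with an estimated correlation). LGR4 changed by -0.85. Hepatic and intestinal markers fell in 11 and rose in 2 of 28, 17 and 6 when adjusted over the list alone (camera adjusted p = 0.00014, but adjusted p = 0.428 with an estimated correlation). The members that rose were ALB and FGA (0.46). Gastric, pancreatic and thyroid markers fell in 2 of 6, 3 when adjusted over the list alone (camera adjusted p = 0.00476, but adjusted p = 0.1 with an estimated correlation). These were TFF1, a trefoil peptide of the stomach (1.46 ± 0.833 against 5.95 ± 1.36 FPKM), and GCG, the glucagon gene, at 1.33 ± 0.301 FPKM in single positive cells and 0 in each double positive library. Without double positive replicate 2, 20 hypoxia genes fell, and 4 hepatic and intestinal markers rose and 16 fell. When double positive replicate 3 was left out, 6 hepatic and intestinal markers and 1 neuroendocrine marker rose. Without single positive replicate 2 the falling members were 5 hypoxia genes and 1 Wnt target, and without single positive replicate 3 they were 4 hypoxia genes, no Wnt target and 5 hepatic and intestinal markers, with no hepatic or intestinal marker rising in either case. Without single positive replicate 1, 3 Wnt targets fell.

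Besides the gastric list, 6 lists passed camera with 4 or fewer changed members, and all 7 calls were lost with an estimated correlation. The mitotic list fell with 1 of 38 members changed, NUSAP1 (-0.28), at a camera adjusted p of 0.00495 (adjusted p = 0.505 with an estimated correlation, and 0.0655 without double positive replicate 1). The replication list fell with 1 of 32 changed, DTL (-0.52), at a camera adjusted p of 0.0438 (adjusted p = 0.674 with an estimated correlation, and 0.0808, 0.427 and 0.236 without double positive replicate 1, double positive replicate 3 and single positive replicate 1). The FGF and ERK target list fell with 4 of 19 changed, led by DUSP5 (-1.07), at a camera adjusted p of 0.0431 (adjusted p = 0.332 with an estimated correlation, and 0.179, 0.0765 and 0.0778 without double positive replicate 2, double positive replicate 3 and single positive replicate 1). The histone list rose with 1 of 10 changed, HIST1H2BD (0.55), at a camera adjusted p of 0.022 (adjusted p = 0.332 with an estimated correlation, and 0.0575 and 0.127 without double positive replicates 1 and 2). The nuclear oxidative phosphorylation list, median 0.12, and the mitochondrially encoded list, median -0.14, each passed at a camera adjusted p of 0.0332 with no member of 32 and 13 passing (adjusted p = 0.772 and 0.167 with an estimated correlation). The oxidative phosphorylation median turned to -0.02 without double positive replicate 2 (camera adjusted p = 0.652). That call was also lost without single positive replicates 1 (0.109) and 3 (0.103) and with the length trend removed (0.184). The mitochondrially encoded call was lost without double positive replicates 1 (camera adjusted p = 0.0643) and 3 (0.103). Over the alternatives with the preset correlation the highest camera adjusted p was 0.0655 for the mitotic, 0.427 for the replication and 0.184 for the FGF list. It was 0.216 for the histone, 0.722 for the oxidative phosphorylation and 0.103 for the mitochondrially encoded list. The lowest values were 1.28e-05, 0.000195, 0.0213, 0.0149, 0.00123 and 0.000114, in the same order. Adjusted over the list alone, 6 FGF and ERK targets and 0 mitotic genes fell, and 2 histone genes rose. Without double positive replicate 2 the counts of members that fell were 8 mitotic genes (camera adjusted p = 2.65e-05), 6 replication genes (camera adjusted p = 0.000721), 5 mitochondrially encoded genes (camera adjusted p = 0.00128) and 1 oxidative phosphorylation gene, and 2 histone genes rose. When double positive replicate 3 was left out, 3 mitotic genes fell and 2 histone genes rose. No mitotic gene passed without any 1 of the other 7 libraries, no replication gene without single positive replicate 2 and no histone gene without single positive replicate 3. The count of FGF and ERK targets that fell was 2 without double negative replicate 1 or single positive replicate 1, 1 without double negative replicate 2 or 3, double positive replicate 1 or single positive replicate 2, and 0 without single positive replicate 3, and 1 rose without double positive replicate 2 or 3.

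Among the lists that did not pass between the gates, airway markers (1 rose and 1 fell of 10, camera adjusted p = 0.139) and immediate early genes (0 and 1 of 27, camera adjusted p = 0.248) passed without double positive replicate 2. Then 5 airway markers fell (camera adjusted p = 0.00543) and 8 immediate early genes fell (camera adjusted p = 0.0146). Both lists also passed with array weights (camera adjusted p = 0.0103 and 0.0204), and the immediate early list with the length trend removed (0.0255).

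In total 1081 genes (8.5% of those tested) passed the limma test, 568 higher and 513 lower in double positive cells, of which 17 and 54 changed at least 2-fold. At an unadjusted p under 0.05 there were 3624, and the 3 and 3 libraries did not overlap for 3926 genes (31%, against 10% by chance). On the TPM scale 250 genes were higher and 557 lower (31% higher, against 52.5%), with a median fold change of all genes of -0.08. The count changed with each library left out, and the cause was not tested. It was 1921 without double positive replicate 2, 710 without replicate 1 and 1765 without replicate 3 of that group, 713, 234 and 209 without single positive replicates 1, 2 and 3, and 564, 503 and 556 without double negative replicates 1, 2 and 3. With only the 6 libraries compared it was 119, in a fit without the double negative libraries, which spread least within their group. Of the named genes, ALB, SLPI, CLCA1, APOB and SPINK1 lost the call without single positive replicate 2 (limma adjusted p = 0.062, 0.0815, 0.0697, 0.0837 and 0.102) and without single positive replicate 3 (limma adjusted p = 0.0655, 0.0723, 0.0725, 0.0627 and 0.0746). CHI3L2 lost it without single positive replicate 2 (limma adjusted p = 0.0519), APOB without single positive replicate 1 (limma adjusted p = 0.0657) and SPINK1 without double positive replicate 1 (limma adjusted p = 0.0531). Over all alternatives the limma adjusted p ranged from 0.00311 to 0.0655 for ALB, 0.00615 to 0.152 for SLPI, 0.00387 to 0.114 for CHI3L2, 0.00182 to 0.0725 for CLCA1, 0.00686 to 0.0907 for APOB and 0.000221 to 0.102 for SPINK1. BEX1 and FKBP2 lost the call only with the 6 libraries (limma adjusted p = 0.0605 and 0.0595, from 0.00287 and 0.00394 at the lowest).

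The comparisons overlapped. Of the 568 genes higher in double than in single positive cells, 323 (56.9%) were also higher in single positive than in double negative cells, where independent lists would share 151, and 57 (10%) were lower there, where independent lists would share 133. Of the 513 genes lower in double positive cells, 242 (47.2%) were lower in single positive than in double negative cells (120 for independent lists) and 130 (25.3%) were higher (137 for independent lists). The comparisons against double negative cells shared 2955 genes higher (1051 for independent lists) and 2542 lower (810 for independent lists). With 3 shared libraries no division into parts of at least 2 was possible. In 50 simulations added after seeing the data, with double positive effects shuffled over genes and the double negative libraries shared, the comparisons against double negative cells shared a mean of 1282 genes higher (at most 1317) and 1019 lower (at most 1086), against 1226 and 977 for independent lists of the simulated sizes. The single positive libraries enter the other pair of comparisons with opposite signs, which would lower the same-direction overlaps.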

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

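The alternatives added after seeing the data were limma-voom on recovered fragments, removal of the gene length trend, and that removal without double positive replicate 2; the others were planned before the data were examined. For named genes, 550 of 550 values against double negative cells, in either comparison, kept direction and call, while between the reporter-positive gates 542 did, 24 lost the call and 6 gained it. Named genes were chosen for the largest changes that had passed, so against double negative cells their calls were likely to hold from the start. For lists that passed, all with the preset correlation, 289 values kept the call and 18 lost it for double positive against double negative cells. For single positive against double negative cells 325 kept and 5 lost it, and between the gates 272 and 32, where 2 changed direction. These values leave out the estimated correlation, with which 3 of 14, 5 of 15 and 4 of 14 lists passed, in that order. The median of the nuclear oxidative phosphorylation list turned to -0.023 without double positive replicate 2, the lowest of its leave-one-out values, which reached 0.214 without replicate 3, and to -0.06 when the length trend was also removed. With the length trend removed and all libraries kept, the median was 0.086 and the call was lost (camera adjusted p = 0.184). The histone list between the gates also lost its call in that setting (camera adjusted p = 0.215). The cause was not tested beyond this.

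With a filter of 5 FPKM fewer genes entered, and the counts of changed genes fell to 4592 (1920 lower) for double positive and 3998 (1633 lower) for single positive against double negative cells. On the TPM scale the counts were 2414 higher and 5785 lower, and 2228 higher and 4846 lower, in these comparisons, and 250 higher between the gates, since the sum of FPKM differed between groups. Between the gates the count of 1081 ranged from 209 to 1921 (95 to 995 higher, 113 to 926 lower) when 1 library was left out. It was 119 (51 higher and 68 lower) with only the 6 libraries compared, and 1818 (868 higher and 950 lower) without double positive replicate 2 and the length trend. The cause was not tested. Fewer libraries give fewer degrees of freedom, but for single positive against double negative cells the count rose from 6344 to 8220 with only their 6 libraries. The SD of a library's deviation from the others of its group was 0.127 to 0.134 for double negative and 0.166 to 0.183 for single positive libraries. It was 0.399 for double positive replicate 2, and 0.269 and 0.258 for replicates 1 and 3, whose deviations are taken in part from replicate 2. With the length trend removed, the difference of replicates 1 and 3 gave an SD of 0.2 for such a deviation. The double negative libraries, with the smallest SDs, do not enter the fit of the 6 libraries of the gates. With voom the counts were 7482, 1231 and 6546 and with the length trend removed 7651, 1267 and 6860, for double positive against double negative cells, between the gates and for single positive against double negative cells. With an estimated correlation 3, 4 and 5 lists passed in that order, against 14, 14 and 15.

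Whether equal replicate numbers mark the same plate is not given in the sources used here, and the libraries were not treated as paired. Of 9 same-number correlations of deviations (-0.017 to 0.166), the 3 of replicate 1 exceeded 0.1 and the other 6 did not. In both other groups at once, 6 of 9 libraries correlated best with their own number, so pairing stays open. With a replicate block the counts were 7417, 897 and 6302, in the order used above. Depth limits what can be said of genes near 3 fragments, which in 1 kb correspond to at most 0.128 FPKM.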

Other observations

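The gene families here, the gene length, depth and run-over tests, and the test of double negative cells in the single positive gate were chosen after the results were seen; the tests of double negative cells in the sorted tube, of a wider stretch of the chromosome, of double positive replicate 2 alone, of length bias in the gut, liver and endocrine genes and of other splits were set before. HOX genes, which set position along the body axis, were low in both reporter-positive groups. All 12 tested members fell in double positive and in single positive cells against double negative cells by limma, under the deposited, TPM and median ratio scales, with the length trend removed and without double positive replicate 2. HOXB9 went from 8.79 ± 1.73 to 0.371 ± 0.063 and 0.218 ± 0.198 FPKM and HOXA11 from 6.62 ± 0.716 to 0.344 ± 0.181 and 0.251 ± 0.0902. Of 372 zinc finger genes named ZNF, 158 fell and 26 rose in double positive cells against double negative cells (257 and 11 on the TPM scale).

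Collagen and laminin genes moved both ways. Of 24 collagen genes 16 fell and 6 rose in double positive against double negative cells (18 and 6 on the TPM scale). COL2A1 of cartilage went from 239 ± 20.9 to 40.4 ± 5.3 FPKM, while COL11A1 went from 1.99 ± 0.668 to 52.7 ± 8.54. Of 9 laminin genes 5 rose and 3 fell (4 and 4 on the TPM scale). LAMB3, a chain of epithelial laminin, went from 6.41 ± 0.695 to 131 ± 9.05 FPKM, opposite to the LAMB1 chain. As for other splits of the 6 libraries of each comparison, 10 exist, too few for a share under 0.05, and 1 of them, the real one, reached the real count in each. Every other split mixed the sorted groups in both parts, so their difference entered the spread and few calls could follow. The splits therefore decide nothing about chance. The real counts were 7407, 1081 and 6344, and the highest of the other splits called 0 by limma, with 532, 1230 and 66 genes at an unadjusted p under 0.05 against 7930, 3624 and 7095 for the real split, for double positive against double negative, double positive against single positive and single positive against double negative cells.

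Double positive replicate 2 stood apart from the other double positive libraries, at 36.5 on the second principal component. Lower depth is argued against by its 1.088 times as many fragments as the mean of the others, although 879 genes stood at 0 against 414 and 379 there, and double negative cells in the sorted tube by a median deviation of -0.074 (quartiles -0.254 and 0.237, 45 genes) over genes at least 8-fold lower in double positive cells, which such cells would raise. Its deviation fell with gene length (Spearman rho -0.477 across genes, which are not independent replicates). Length was not the whole cause, since with the trend removed the SD was 0.35, or 1.757 times the 0.2 expected from replicates 1 and 3, with 22.8% of the variance removed, and MALAT1, a long nuclear RNA, stood at 445, 916 and 476 FPKM in replicates 1 to 3. A loss of long transcripts in that library may explain part of the pattern, while lower library complexity, RNA quality and a difference between cultures stay open.

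LGI3 (chromosome 8, 22146825 to 22157084, minus strand, overlapping SFTPC, singled out after its values were seen) lay at 7.16 ± 2.53 against 1.7 ± 0.578 FPKM in double and single positive cells, and BMP1 (22164736 to 22212326), on the other side of SFTPC, at 10.8 ± 1.89 against 4.73 ± 0.559. Reads running over from SFTPC stay open, since the fragments above the double negative level per 100 SFTPC fragments were 0.66 against 1.39 for LGI3 (a ratio of 0.477) and 1.15 against 1.94 for BMP1 (0.591), which a constant share of run-over together with expression of the genes' own in both gates would also give. A wider stretch of the chromosome moving together also stays open, since of 8 other tested genes within 250 kb (log2 fold changes of -0.40 to 0.60) limma called 0 higher, with 2 at an unadjusted p under 0.05 and 0 by voom, but NUDT18 (0.60, limma adjusted p = 0.0508) and REEP4 (0.35, limma adjusted p = 0.0868), both singled out after their values were seen, passed without double positive replicate 3, and NUDT18 without single positive replicate 3. Local activity shared around SFTPC may contribute, and the strand setting that would bear on LGI3 is not given in the sources used here.

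The neuroendocrine, hepatic and intestinal list members higher in single than in double positive cells numbered 17, among them CHGA, APOA4, MUC13 and CDX2, while ALB and FGA of the same lists were lower. Double negative cells in the single positive gate were tested as an admixture with the average levels of that group. At the share of 3.26% that the 5th percentile of double negative genes allows, they account for 0% of the genes. At the median share of 9.98% they account for 3 genes (17.6%), which need 3.6 to 8.7%. An average admixture is thus argued against as the source of the set and stays open for those 3, CDX2 among them. The test could not address a subset of double negative cells richer in these genes, which stays open. The other genes need at least 15.2%, and limma called 7 of the 17 genes higher and 7 lower in single positive than in double negative cells. Double positive replicate 2 alone and gene length bias are argued against by 0% and 0% of the genes losing the call without that library or with the length trend removed, although 7, 5 and 3 genes lost it without single positive replicates 3, 2 and 1, 3 without double negative replicate 1, 2 or 3, 2 without double positive replicate 1 and 1 without double positive replicate 3. For the genes higher in single positive than in double negative cells, a minority of cells with a gut, liver or endocrine fate may be the source, a hypothesis that bulk libraries cannot separate from low expression in all cells.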
